A study of Mus musculus with 4 samples.

How the data were processed

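Gene expression was measured on 4 single-colour microarrays. The RNA came from C17.2 cells, an immortalised mouse line of multipotent neural progenitors. Every culture had received 7.38 mM AAPH, a water-soluble azo compound that breaks down into peroxyl radicals, for 12 h. In 2 of the 4 samples the medium also held 1.69 µM berberine, a plant isoquinoline alkaloid. Per the labels, total RNA was column-purified, amplified and labelled with Cy5. The scanner, the image software and the array's background correction are not given in the sources used here.

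The main input was the deposited table of probe values, a linear intensity for each of 26423 probes on each array, with the authors' background handling and scaling unstated. Whether it had been normalized between arrays is not stated. The array medians differed (333 and 273 in the controls, 189 and 206 with berberine), and it was therefore normalized here, but its group means lie close to those that the authors' workbook heads as normalized, so the values may already be the authors' normalized ones and results on them as deposited are given as an alternative. The deposited workbook added a sheet of 9800 probes that the authors had called changed. Per the file headers it gives a detection p-value and a mean normalized intensity for each group, a log2 ratio and its p-value. How the authors computed that ratio and those p-values is not given in the sources used here. Among the 9765 probes with a ratio none lay between −1 and 1, and the largest p-value in the sheet was 0.0499. For the other 35 probes the sheet gives no ratio. Further sheets list 406 biological process terms with the authors' p-value and Benjamini q-value, and the called genes under each term.

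The sheet calls its groups G1 and G3 without saying what they are. Its G1 means differed from the mean of the control arrays by a median of 0.273%, with 99.9% of probes within 5%, and its G3 means from the mean of the berberine arrays by 0.661%, with 99.2% within 5%. The crossed matching gave 94.6% and 74.6%. G1 was therefore read as AAPH alone and G3 as AAPH with berberine. The whole-series tables held 0 columns of per-sample values that belong to no sample.

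Gene names came only from the sheet of called probes. Of its 9800 probes, 9190 had 1 gene symbol and stood for 8519 genes, 83 had several symbols and 527 had none, and the other 16623 probes on the array stayed unnamed. Entrez identifiers of 9121 probes were found in a mouse gene table of assembly GRCm38.p6, where the symbol of 602 single-symbol probes differed from that in the sheet. The sheet's symbols are printed. No genome build is named in the sources used here, so no coordinates are given.

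Intensities were floored at 1, log2-transformed and quantile-normalized, because the median log2 values of the arrays differed by more than 0.1. Berberine was compared with control using lmFit and eBayes of limma 3.58.1 in R 4.3.3 over all 26423 probes, 2 arrays against 2, with 2-sided p-values adjusted by Benjamini-Hochberg and a threshold of 0.05. All adjusted p-values of single genes come from this limma fit. The plan had been to fit named genes, but the names cover only probes the authors had already called, so the adjustment runs over all probes and gene counts describe the named subset. Each gene was represented by its named probe with the highest mean over the 4 arrays. Log2 fold changes are berberine minus control and are followed by the standard error of the fit. Quantile normalization moved the median log2 difference of all probes to 0.39, against 0.13 for the values as deposited and 0.74 after median centring, and changes are relative to that shift.

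A probe was taken as at background in a group when the authors' detection p-value there was 0.01 or more. For such a probe the text gives a bound, "at least N-fold". It is the mean of the group in which the probe was detected, set against the mean over the dim arrays of the higher of the probe's own value and the array's background limit, all as normalized log2 values. The limit was the lowest value among probes detected in that group (log2 6.66 and 6.55 on the control arrays, 7.31 and 6.81 on the berberine arrays). As the lowest detected value, it is not an upper edge of the background. The bound therefore follows a rule and is not a confidence limit. Where a probe's own values lie above the limit, the bound equals the fitted fold, as for Rfc3 (24.5-fold). Fitted fold changes of such probes depend on background signal, on the normalization and, for values below 1, on the floor. They have no meaningful order among themselves. Values below 1 numbered 490 and 0 on the berberine arrays and 1160 and 18 on the control arrays.

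Before the data were examined, 34 gene lists (835 genes) on redox, stress, death, cell cycle, lipid, mitochondrial, inflammatory and neural themes and on markers of other cell types were fixed, of which 442 genes were measured under a name. A member without a called probe has no name here, so counts of measured members do not describe whole lists. The 30 lists with at least 5 measured members were tested with camera in limma at a preset inter-gene correlation of 0.01, 2-sided and adjusted over the lists. Because named probes had been chosen by the authors on these same arrays, counts of changed members are not independent evidence, and the camera test compares a list only with other called genes. The genes named in the text were also fixed by rule. They are the 8 largest rises and 8 largest falls in fitted log2 fold change among genes past the threshold whose berberine arrays both lay beyond both control arrays and whose mean was above the median of the genes tested, up to 3 members with the smallest adjusted p from each list described with examples, and 9 genes fixed beforehand, among which Gclm, Nes and Sox2 had no named probe. Some genes that the rule takes are not reported here. Other genes are said to have been picked after their values were seen.

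The steps were tested on simulated arrays with the 26423 probes and their spread. Of 40 probes simulated at each size, the limma step recovered 35 at log2 4, 25 at log2 2, 16 at log2 −2 and 0 at log2 1 or −1, with 4 false calls. The list step found the shifted list and made 0 false calls among 20 lists. All simulated arrays were drawn from the mean control levels, and only few probes were shifted. On the real arrays most probes were called and the intensity distributions of the groups differed, so these rates do not carry over. Alternatives covered the normalization, filters on dim probes, a pseudocount of 50, the variance prior, the test, the probe rule, the replicate number as a block, each array left out, and the set test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision. The labels do not say that the samples of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.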

Results

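C17.2 mouse neural progenitor cells damaged with AAPH, a source of peroxyl radicals, were compared with cells given the same damage together with berberine. Each group had 2 arrays of 26423 probes. The median intensity was 333 and 273 on the AAPH-only arrays, called controls here, and 189 and 206 on the berberine arrays, while the 99th percentile was higher with berberine (96496 and 83026) than in the controls (66711 and 54628). The comparison asks which transcripts berberine altered in oxidatively damaged neural progenitors.

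With berberine, most measured genes of the respiratory chain, mitosis and lysosomes had a lower probe signal, some down to the array background. Such falls were not particular to these lists. Of the 852 named genes brightest in the controls 84.2% fell, and of the 852 brightest by the mean over all 4 arrays 36.9% fell. Changes given here are in probe signal and need not be changes of whole transcripts. Of pairs of named probes with identical RefSeq transcript accessions, 47.3% moved in opposite directions, against 49.7% for named probes paired at random. Handling of the berberine samples cannot be told apart from berberine itself. Levels of Gpx4, the peroxidase that reduces lipid hydroperoxides in membranes, dropped from intensities of 140195 and 103994 to 120 and 115. By the bound rule this was a fall of at least 1040-fold, close to the fitted 1060-fold (n = 2 per group, adjusted p from limma 0.000186). Itga5, a fibronectin receptor subunit, went the other way, from 2068 and 1799 to 23900 and 23433 (16.3-fold, log2 4.03 ± 0.139 SE, adjusted p = 0.000282). The limma fit called 16578 of the 26423 probes, 10635 higher and 5943 lower. Fitted falls of 16-fold or more numbered 1367 and fitted rises of that size 9. The fitted fall of a probe at background depends on background signal and normalization, and for few probes on the floor. On the values as deposited, without quantile normalization, 8770 probes were called, and the split turned to 3534 higher and 5236 lower. Of the 8519 named genes, all of which the authors had already called, 8493 passed, 4739 higher and 3754 lower. With genes at background in a group taken at their bound, 881 named genes were at least 16-fold lower and 5 at least 16-fold higher.

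The 8 falls taken by the naming rule, which ranks fitted fold changes, were in genes bright in the controls and, by the authors' detection p-value, at background in the berberine group. Their order carries no meaning, and some genes outside the 8 have larger bounds than some of these. Hist1h2ao, a core histone H2A gene, was at least 835-fold lower. Prep, a prolyl endopeptidase, was at least 655-fold lower, and Tnfrsf12a, the receptor of the cytokine TWEAK, at least 611-fold. The chaperonin subunits Cct6a and Cct3, which fold actin and tubulin, were at least 505-fold and 266-fold lower. Ddost, a subunit of the N-glycosylation complex, was at least 477-fold lower, and Ahsa1, an activator of the Hsp90 ATPase, at least 463-fold. Adjusted p-values of these 7 genes ran from 0.000186 to 0.000389.

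**Figure D1:**
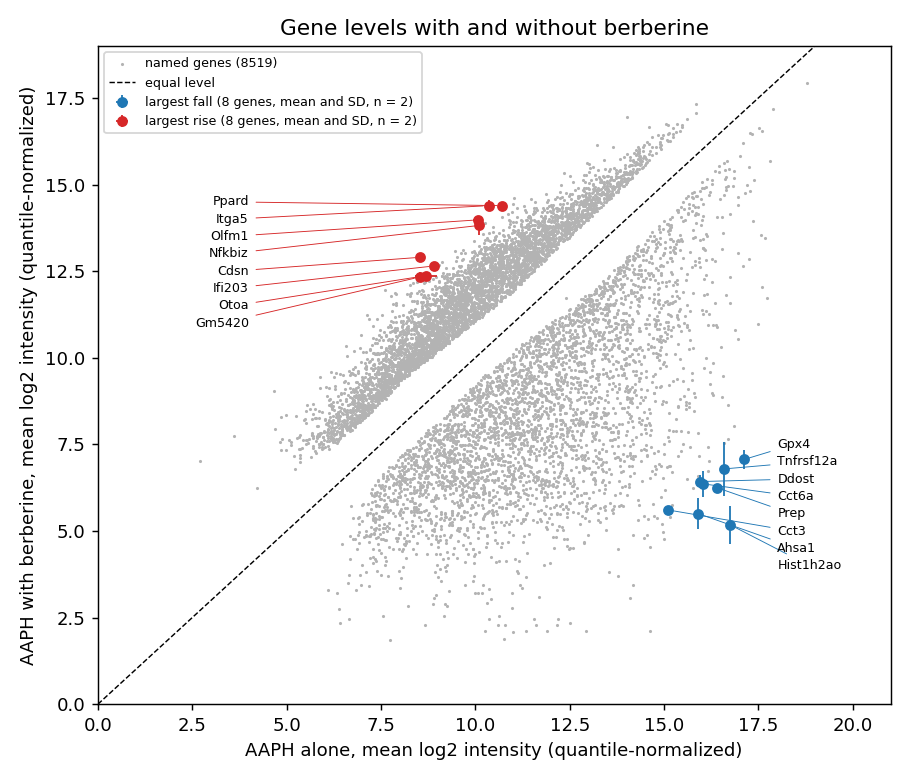
Mean log2 intensity after quantile normalization in the 2 control arrays (x axis) and the 2 berberine arrays (y axis) for each of the 8519 named genes (grey). The 8 falls (blue) and 8 rises (red) largest by fitted fold change under the naming rule carry bars of 1 SD, and the gap along the dashed line of equal level arises because names exist only for probes the authors had called changed.

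The largest rises were smaller and were measured above background in both groups. Cdsn, which encodes the epidermal adhesion protein corneodesmosin, rose 20.5-fold (log2 4.35 ± 0.110). Olfm1, a secreted neuronal olfactomedin, rose by 3.90 ± 0.136 on its brightest named probe, but its other named probe fell by 4.03, and the mean of both probes gave −0.062. Ifi203, an interferon-inducible gene, rose by log2 3.74 ± 0.116 and Nfkbiz, an inhibitor of NF-κB in the nucleus, by 3.71 ± 0.178. Ppard, the fatty acid-sensing nuclear receptor PPARδ, rose by 3.67 ± 0.113. The inner-ear gene Otoa rose by 3.67 ± 0.193 and the predicted gene Gm5420 by 3.80 ± 0.128. Adjusted p-values from limma ran from 0.000189 to 0.000584 for the 7 rises given here.

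Most measured genes of the respiratory chain fell. Complex I is the NADH dehydrogenase that berberine is known to inhibit in isolated mitochondria. Of its 37 listed genes 22 were measured, of which 19 fell and 3 rose. The median log2 fold change was −3.50, or −3.04 with genes at background taken at their bound. The camera adjusted p was 0.00243, or 0.702 with an estimated correlation, with which a list can hardly pass on 4 arrays. Ndufb5 was at least 105-fold lower, Ndufa8 fell by 7.36 ± 0.110 on the log2 scale, and Ndufb11 was at least 51.4-fold lower. Of 37 listed genes of complexes II to V 16 were measured, of which 15 fell and 1 rose. Their median was −2.79 (camera adjusted p = 0.00593, or 0.702 with an estimated correlation). There the succinate dehydrogenase subunit Sdhb fell by 7.67 ± 0.169, the ATP synthase subunit Atp5j2 by 5.97 ± 0.133 and the cytochrome oxidase subunit Cox5a by 4.39 ± 0.153. The representing probe was at background with berberine in 6 members of complex I and 3 of complexes II to V. Both lists were brighter in the controls (median log2 14.17 and 15.55) than the named genes as a whole (10.5). Of the 852 named genes brightest in the controls (median log2 14.73), 84.2% fell, with a median log2 fold change of −2.97. Of the 852 brightest by the mean over all 4 arrays, 36.9% fell. Among random lists matched on control level, added after the data were seen, the list medians lay at percentiles 7.40 and 30.7. Both lay at percentile 0 when matched on the mean over all arrays.

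Mitotic genes were lower as well. Of 33 listed G2/M and mitosis genes 19 were measured, of which 16 fell and 3 rose. The median was −2.67, or −2.58 with bounds (camera adjusted p = 0.00724, or 0.702 with an estimated correlation). That estimate was −0.0483, below the preset 0.01, so a higher correlation is not what removed the call. Top2a, the topoisomerase that untangles chromosomes before division, was at least 171-fold lower, Birc5 (survivin) fell by 6.29 ± 0.119, and the spindle motor Kif11 was at least 16.5-fold lower. The probe was at background with berberine in 8 of the 19. Without genes at background in either group, a filter that the fall itself decides, the median was −1.78 and the camera adjusted p 0.0512. Genes of DNA replication and G1/S did not pass camera as a list. Of these, 11 of 18 rose and 7 fell, the median (1.23) and mean (−0.58) had opposite signs, and the camera adjusted p was 0.761. Its members with the smallest adjusted p fell, namely Mcm7 of the replicative helicase (at least 113-fold), Rfc3 of the clamp loader (at least 24.5-fold) and Gins2 (at least 15.6-fold).

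In the autophagy and lysosome list of 28 genes, 17 were measured, of which 13 fell and 4 rose. The median was −3.71 (camera adjusted p = 0.0474, or 0.702 with an estimated correlation). The autophagy receptor Sqstm1 (p62) was at least 188-fold lower, and the lysosomal protease Ctsd fell by 8.16 ± 0.175. This call ended when a berberine array was left out (adjusted p = 0.0616 without replicate 1 and 0.0654 without replicate 2), without genes at background in either group (0.113), with the mean of a gene's probes (0.0701), without genes whose probes disagreed (0.0704) and with each gene's dimmest probe (0.119). The median stayed between −3.56 and −3.91 under these changes, except −1.86 without genes at background, a filter that the fall itself decides. The probe was at background with berberine in 5 of the 17.

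**Figure D2:**
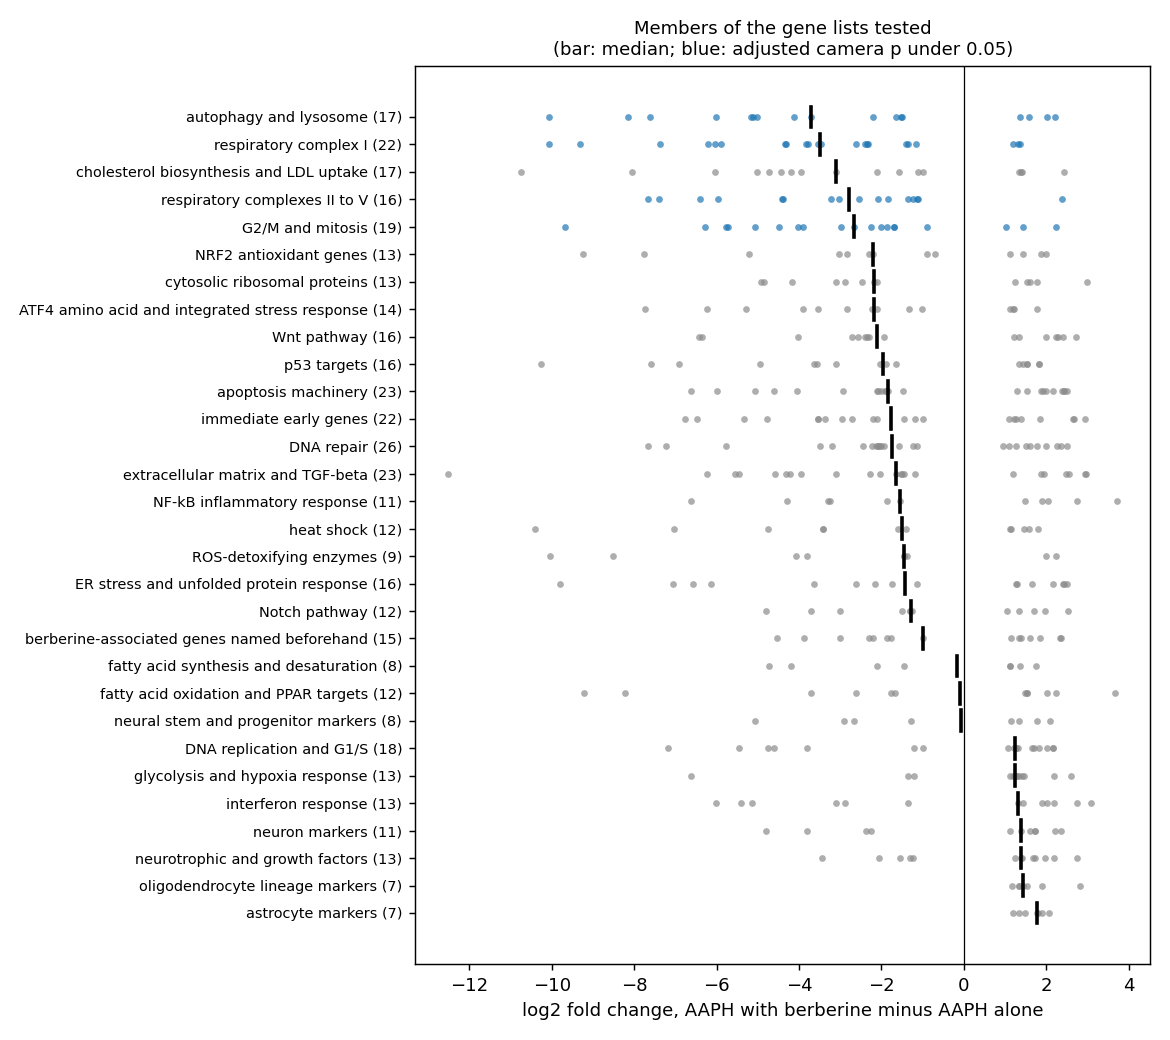
Log2 fold change (berberine minus control) of each measured member of the 30 tested gene lists, with the number of members in brackets, the median as a bar and the 4 lists with a camera adjusted p under 0.05 in blue. All 4 had medians below 0, from −2.67 to −3.71, and no member lies near 0 because names exist only for probes the authors had called.

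Whether sterol genes passed as a list depended on the processing. In cholesterol biosynthesis and LDL uptake, 13 of 17 genes fell and 4 rose, with a median of −3.10 and a camera adjusted p of 0.0752, and the probe was at background with berberine in 5. The list passed on the values as deposited (0.0133), under the stricter of the filters on dim genes (0.0396) and with each gene's dimmest probe (0.0477), but not under the milder filter (0.0689) or with an estimated correlation (adjusted p = 0.702). Squalene epoxidase Sqle was at least 234-fold lower and the sterol methyl oxidase Sc4mol fell by 4.72 ± 0.121.

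None of the stress lists tested passed camera, which compares a list with other called genes. With fry, which asks only whether a list's genes move on balance, each passed (adjusted p from 0.000706 to 0.0028), as did most other lists. Members have names only because the authors had called them changed on these same arrays. A pass with fry was therefore likely from the start and is not independent evidence. Of 13 NRF2 antioxidant genes 9 fell and 4 rose (median −2.20, or −1.25 with genes at background taken at their bound, camera adjusted p = 0.26). Gclc, the catalytic subunit for the rate-limiting step of glutathione synthesis, was at least 17.6-fold lower and the glutathione transferase Mgst1 at least 19.6-fold, and G6pdx of the pentose phosphate pathway fell by 5.22 ± 0.112. Hmox1, the haem oxygenase induced by oxidants, fell by 2.20 ± 0.238 and the quinone reductase Nqo1 was at least 4.40-fold lower. Among 9 ROS-detoxifying enzymes 7 fell and 2 rose (camera adjusted p = 0.165), with the mitochondrial peroxiredoxin Prdx3 at least 13.3-fold lower and Prdx5 down by 4.07 ± 0.204 in log2. In the ATF4 list 10 of 14 fell and 4 rose (camera adjusted p = 0.115). Its members Psph of serine synthesis and Aldh18a1 of proline synthesis were at least 83.4-fold and 35.1-fold lower. The stress-induced transcription factor Ddit3 (CHOP) fell by 5.29 ± 0.157, and Atf3 was at least 4.11-fold lower. Probes at background with berberine numbered 4 in the NRF2 list, 3 among the ROS-detoxifying enzymes and 4 in the ATF4 list. Among random lists matched on control level, added after the data were seen, these 3 medians lay at percentiles 12.5, 70.2 and 18.4. Matched on the mean over all arrays they lay at 2.53, 22.8 and 1.93.

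The ER chaperone Hspa5 (BiP) fell by 7.06 ± 0.141 and the disulfide isomerase Pdia4 by 6.57 ± 0.121, and the co-chaperone Dnajb11 was at least 28.9-fold lower. In their list of ER stress genes 9 of 16 fell and 7 rose (camera adjusted p = 0.504). Of 12 heat shock genes 7 fell and 5 rose (0.465), among them the co-chaperones Stip1 (−4.76 ± 0.144) and Hspe1 (−7.04 ± 0.241). In the p53 target list 10 of 16 genes fell and 6 rose (camera adjusted p = 0.271). Phlda3, an Akt inhibitor, was at least 247-fold lower and the zinc finger gene Zmat3 at least 52.8-fold. Trp53inp1 fell by 4.95 ± 0.154 and Cdkn1a, the p21 cell cycle inhibitor, fell by 3.10 ± 0.111. Of 23 genes of the apoptosis machinery 13 fell and 10 rose (0.504), with the BH3-only gene Bad at least 67.8-fold and the mitochondrial protease Htra2 at least 53.9-fold lower, and the nuclease Endog down by 4.06 ± 0.164. Probes at background with berberine numbered 1 in the ER stress list, 1 in the heat shock list, 5 among p53 targets and 3 in the apoptosis list. Among random lists matched on control level, these 4 medians lay at percentiles 48.2, 92.7, 16 and 8.44, in the same order. Matched on the mean over all arrays they lay at 6.49, 3.09, 3.41 and 2.03.

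Glial markers went up without passing camera as lists. Of 14 listed astrocyte markers 7 were measured, and all 7 rose, with a median log2 fold change of 1.77 (camera adjusted p = 0.111). Among them Sparcl1 rose by 2.06 ± 0.131, the growth factor receptor Fgfr3 by 1.89 ± 0.109 and S100b by 1.80 ± 0.120. None of the 7 was at background in either group. Of 16 listed oligodendrocyte lineage markers 7 were measured, and all 7 rose too, with a median of 1.44 (camera adjusted p = 0.111). Here Pdgfra of oligodendrocyte precursors rose by 2.82 ± 0.110, the myelin gene Mbp by 1.44 ± 0.117 and the lineage factor Olig2 by 1.35 ± 0.114. On the values as deposited, where Sparcl1 and Pdgfra still passed, the others named here kept their sign but were smaller and lost their call, with log2 0.95 for Fgfr3 (adjusted p = 0.0507), 0.85 for S100b (0.0559), 0.84 for Mbp (0.0627) and 0.35 for Olig2 (0.343). The glial medians lay within those of random lists of named genes matched on control level, a comparison added after the data were seen. They lay at percentile 81.3 for astrocyte markers (matched median 1.46) and 68.7 for oligodendrocyte markers (1.32). These lists were not matched on the series of the probe, read from the prefix of its identifier. All glial genes named here except Pdgfra are represented by PH_mM probes. In that series 65.9% of genes rose, against 43.1% for the mMC series. The 3 measured endothelial markers rose too, with a median of 1.33, but on the values as deposited all lost their call, with log2 0.62 for Cldn5 (adjusted p = 0.0992), 0.30 for Esam (0.408) and 0.70 for Cdh5 (0.0945). Neural stem and progenitor markers were split, 4 higher and 4 lower of 8 (median −0.07, camera adjusted p = 0.761). Their member Sox9, a stem cell and glial transcription factor, was at least 5.15-fold lower, Bmi1 fell by 2.91 ± 0.114 and Id2 by 2.66 ± 0.133. Of 11 neuron markers 7 rose and 4 fell, with a median of 1.38, a mean of −0.10 and a camera adjusted p of 0.761. The neurofilament gene Nefl rose by 2.21 ± 0.140, Map2 fell by 3.79 ± 0.140 and Ncam1 was at least 20.3-fold lower. The probe was at background with berberine in 1 of the stem and 2 of the neuron markers.

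In the authors' deposited sheet, 1808 of 9800 called probes (18.4%) were detected in the controls only, 423 with berberine only, 7516 in both groups and 53 in neither.

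Different probes for a gene often disagreed. Of 442 pairs of named probes that carried identical RefSeq transcript accessions, 209 (47.3%, exact 95% binomial interval 42.5 to 52.1) moved in opposite directions, against 49.7% for named probes paired at random. Across those pairs the log2 fold changes had a Pearson r of 0.139 and a Spearman rho of 0.115, with a 2-sided permutation p of 0.0034 for r. Pairs share arrays and are not independent replicates. Among members of the lists that passed, probes of 1 gene moved apart for 1 of the 2 complex I genes with several named probes, 2 of the 4 mitotic genes and 1 of the 1 lysosomal gene.

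**Figure D3:**
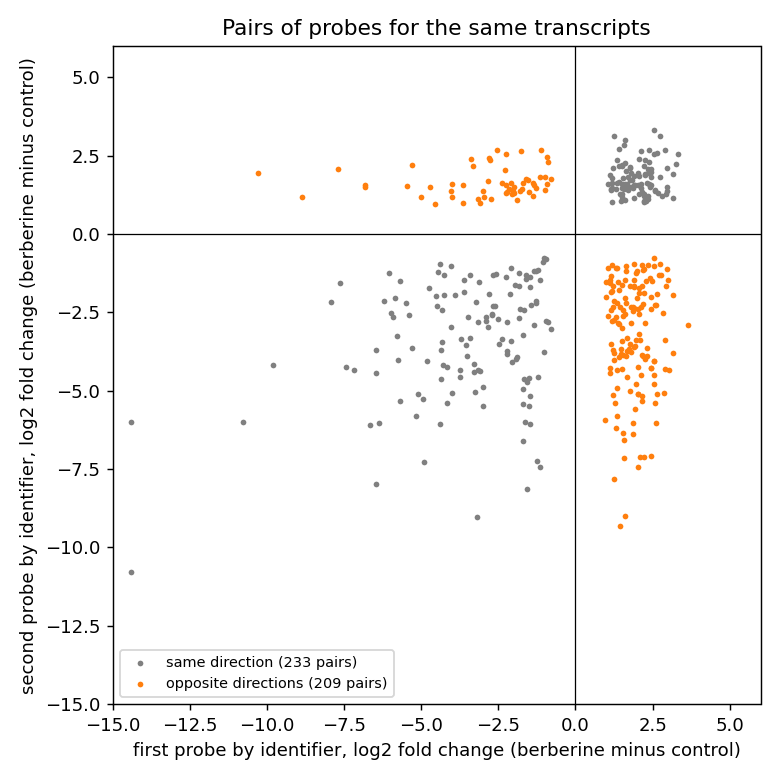
Log2 fold change (berberine minus control) of the first (x axis) and second (y axis) probe, in order of identifier, for 442 pairs of named probes with identical RefSeq accessions. The 209 pairs in orange moved in opposite directions.

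In the authors' deposited table, 5436 ratios were above 0 and 4329 below, with a floor at log2 −6.64. The refit gave the same sign for 99.99% of the 9765 ratios, with a Pearson r of 0.994 and a Spearman rho of 0.993 across probes of the same arrays, and 9772 of the 9800 probes passed its threshold. The sheet holds only probes called on these arrays, with no ratio between −1 and 1. Such agreement was therefore close to fixed beforehand and is not independent evidence. A further 2351 probes outside the sheet passed and differed at least 2-fold in the refit. Of the 406 biological process terms in the authors' deposited table, 79 had a q-value under 0.05. Transcription led by the authors' q-value in that table (1008 of 1885 genes called, q = 3.6e-36), followed by the response to DNA damage (277 of 420, q = 3.81e-25), regulation of transcription (1118 of 2279, q = 2.56e-21), DNA repair (209 of 318, q = 2.53e-18) and cell cycle (352 of 614, q = 4.86e-17). Those terms count genes in either direction. In the refit 102 of the DNA repair members fell and 106 rose, and 186 cell cycle members fell and 163 rose. No term differed from the other listed genes in its share of falls after adjustment (2-sided Fisher's exact test, added after the data were seen; 0 of 406 terms, with 22 leaning to falls and 8 to rises at an unadjusted p under 0.05).

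Replicates were close. Across all probes the Pearson correlation of normalized log2 values was 0.989 between the control arrays and 0.987 between the berberine arrays, against a mean of 0.832 over the 4 pairs between groups. The SD of log2 differences was 0.489 and 0.547 within groups and 1.95 between them. Probes are not independent replicates, and the correlations describe these arrays only.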

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

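Leaving out genes at background, genes with disagreeing probes or all but the dimmest probe, the test on all probes, bounds in counts and medians, and level matching were chosen after the data were seen. With the values as deposited, 8770 probes changed and 3534 rose, and replicate correlations were 0.967 (control), 0.974 (berberine) and 0.823 (between groups). In the brighter 13211 probes they were 0.997, 0.992 and 0.555. Lists passing camera numbered 0 with an estimated correlation and 2 without genes at background. With the estimate camera has only the residual degrees of freedom of the 4 arrays, so the 0 was likely from the start. The estimate was above the preset 0.01 for complex I (0.167) and complexes II to V (0.0404). It was below that for mitosis (−0.0483) and for autophagy and lysosome (−0.00834). Under fry, a different test that asks only whether a list's genes move on balance, 29 lists passed. As all members had been called on these arrays, that was likely from the start. The direction of 4 lists turned, with these adjusted p-values. DNA replication gave 0.944 on values as deposited, 0.0136 with fry and 0.946 with rank-based camera. Neuron markers gave 0.0161 and 0.962 with fry and rank-based camera. Interferon response gave 0.763 under the stricter filter on dim genes and 0.462 without genes at background. Fatty acid synthesis gave 0.824 with the mean of probes and 0.78 with the dimmest probe. Medians turned to 0.12 for berberine-associated genes after median centring and to 0.019 for neural stem markers without control replicate 2 (range −0.18 to 0.019 with an array left out). Olfm1 gave −0.062 as the mean of its probes, and −3.98 and −3.66 without berberine replicate 1 or 2, where its other probe became the brightest (range −3.98 to 4.21 with an array left out). The cause of the other turns was not tested. Across all alternatives, named genes kept direction and call in 1524 comparisons and lost the call in 14, and lists kept both in 494, lost the call in 11 and gained it in 26. List medians stayed within the spread over array pairs in 119 comparisons and moved beyond it in 89. No list member changed sign on the values as deposited, and Fth1 did after median centring.

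With an array left out, 7770 to 8382 named genes, 11555 to 15508 probes (7110 to 9516 higher, 4445 to 5992 lower) and 3 to 4 lists passed, the lone sample of a group being assumed to vary like the other group. The replicate numbers did not pair the arrays (correlation of deviations −0.016). With the replicate block 8465 genes, 15558 probes and 4 lists passed. Dim signal limits the falls, since probes at background give bounds only. The workbook's per-array values and a wider background for the process terms were not run, because the workbook gave group means and members for called genes only.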

Other observations

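Of the tests below, the opposite-pair share, its correlation, the prefix of the probe identifier, the order of paired probes, the control level of lost probes, the machinery genes, the level-matched random lists and the regrouping of arrays were chosen after those results had been seen.

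Other gene lists did not pass camera. In the extracellular matrix and TGF-β list 16 of 23 genes fell and 7 rose (camera adjusted p = 0.111), with fibronectin, Fn1, at least 191-fold, Col3a1 at least 45.1-fold and Tgfb2 at least 26.3-fold lower. Of 13 glycolysis and hypoxia genes 10 rose and 3 fell (0.361), including the angiogenic factor Vegfa (log2 2.20 ± 0.139) and the glycolytic activator Pfkfb3 (2.59 ± 0.111), while the collagen hydroxylase P4ha2 was at least 4.31-fold lower. Of 22 immediate early genes 14 fell and 8 rose (0.26), with Dusp6 at least 85.1-fold and Klf4 at least 16.5-fold lower and Cyr61 at −6.47 ± 0.214. Of 16 Wnt pathway genes 9 fell and 7 rose (0.613), among them Ccnd1 (−6.43 ± 0.113), β-catenin, Ctnnb1 (−6.35 ± 0.121), and Nkd2 (−4.02 ± 0.144). Of 15 genes linked to berberine beforehand 8 fell and 7 rose (0.761), with the deacetylase Sirt1 at least 10.2-fold lower, Hdac4 at −3.88 ± 0.139 and Nfe2l2, which encodes NRF2, at −3.00 ± 0.120. Probes at background with berberine numbered 4, 1, 7, 1 and 3 in these lists, in the order given.

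The lists left gave camera adjusted p-values of 0.26 for DNA repair (16 of 26 fell, 10 rose), 0.402 for cytosolic ribosomal proteins (8 of 13 fell, 5 rose), 0.613 for the Notch pathway (7 of 12 fell, 5 rose) and 0.733 for NF-κB inflammatory genes (6 of 11 fell, 5 rose). The value was 0.761 for fatty acid synthesis (4 of 8 fell, 4 rose), fatty acid oxidation (6 of 12 fell, 6 rose), neurotrophic factors (5 of 13 fell, 8 rose) and the interferon response (6 of 13 fell, 7 rose). Lists with too few named members to test were metallothionein and metal response (3 of 4 fell, 1 rose), microglia (2 of 4 fell, 2 rose), endothelium (3 of 3 rose) and fibroblasts (2 of 3 fell, 1 rose).

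Probes for the same transcripts moved in opposite directions in 47.3% of pairs with identical RefSeq accessions, close to the 49.7% of random pairs, which argues against a change in the level of whole transcripts as the account of many calls. Noise in dim probes does not account for it, since 46.0% of pairs bright in their higher group moved apart, and array-wide scaling, which keeps the order of probes that share a change, does not account for the 95 of 209 opposite pairs (45.5%, exact 95% interval 38.6 to 52.5) whose order turned on every array, while for the others normalization cannot be told apart, since the deposited values (47.3% opposite) may already be normalized. Nor does the prefix of the identifier alone, with 53.3% of pairs of the same prefix opposite and 37.6% (exact 95% interval 30.3 to 45.4) of pairs of different prefixes, which is below the share of random pairs, although 65.9% of genes represented by a PH_mM probe rose against 43.1% for mMC and 40.1% for mMR, and in 139 opposite pairs of PH_mM probes the lower-numbered probe was the riser in 114 (exact binomial p = 8.91e-15). An effect on single probes, such as the part of the transcript that was labelled or what else the probe binds, may be the reason, as r between paired log2 fold changes was 0.139. Named pairs exist only where both probes had been called, so pairs in which a probe did not move are not counted.

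Abundant constitutive transcripts sat at background with berberine, including the proteasome gene Psmb7 (13325 and 10354 in the controls, 3 and 46 with berberine) and the initiation factor Eif3b (67658 and 54018 against 81 and 106), both picked after their values were seen. A dimmer scan or less labelled RNA would take the dimmest probes first, but 641 of 1808 listed probes detected in the controls only (35.5%, exact 95% interval 33.2 to 37.7) were brighter there than the median listed probe detected in both groups. Second probes of the same transcripts rose in 96 of 220 cases (43.6%, exact 95% interval 37.0 to 50.5), which argues against loss of whole transcripts for those cases only. They rose less often than listed probes as a whole (5436 ratios above 0, 4329 below), so loss stays open for the others. Second probes were seen only if themselves called, and genes with 3 named probes were counted repeatedly, so the interval is too narrow. The same 43.6% counts against RNA of another mouse cell population. So do 20 of 74 named genes of 7 machineries that every cell needs, which had a probe at background with berberine only. RNA of another organism, degraded RNA or another labelling cannot be told apart without probe sequences, which were not used here, and the level of paired probes correlated at 0.383 in the controls and 0.0388 with berberine. Berberine itself was applied in both affected samples, so whatever separated them in handling is confounded with it.

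The lists that fell differed in their level in the controls, which may set the size of a fall. Among 10000 random lists of named genes matched on control level, the median of complex I lay at percentile 7.40 and that of complexes II to V at 30.7, but both lay at percentile 0 among lists matched on the mean over all 4 arrays. Control level enters the fold change itself, and a large fall lowers the mean over all arrays, so for the respiratory lists the explanation stays open. For mitosis the median lay at percentile 1.67 on control level and 1.32 on the mean of all arrays. For autophagy and lysosome it lay at 1.26 and 0.01. Some lists that did not pass camera also lay low, such as the Wnt pathway (2.19 and 2.75), the ATF4 list (18.4 and 1.93) and apoptosis machinery (8.44 and 2.03). With no adjustment for the 30 lists compared, level alone is not excluded for mitosis or for autophagy and lysosome. A biological shift of those genes stays open, and it rests on probes subject to the disagreement between probe pairs.

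The real split gave 16578 probes and the highest of the other splits of the 4 arrays 0 (limma, with 105 and 97 probes at an unadjusted p under 0.05 in those splits). Of the 3 splits, 1 reached the real count, and 3 are too few for a share under 0.05.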
